A study of Mus musculus with 7 samples.

How the data were processed

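RNA was measured in 7 single mouse oocytes arrested at metaphase of the second meiotic division (MII), with 1 oocyte per library. Per the labels, 3 oocytes carried floxed Hira alleles without Cre (WT1, WT2 and WT4) and 4 carried the same alleles with Cre under the oocyte-specific Zp3 promoter (KO1 to KO4). The cDNA was made and amplified directly on each oocyte with an ultra-low-input kit, ERCC spike-in RNA was added before cDNA synthesis, and barcoded libraries were sequenced on 2 lanes. The labels give no lane per library, no animal, no strain, no age and no day, so none of these could be compared or used as a block.

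The deposited table holds FPKM (fragments per kilobase of gene and scaled to the reads of the library) that the authors computed, with 1 value per Ensembl gene and oocyte, not logged. The submitters' notes list Bowtie 0.12.8, TopHat2 2.0.2, TopHat, Bowtie2, HTSeq, edgeR 3.1.10 and the mm9 build without saying which step each served. The table has 37620 gene identifiers, of which 19320 were at 0 in every library and 18300 had a value in at least 1. Symbols came from a reference annotation on a later build, which was used for names, transcript GC content and the order of neighbouring genes, and no coordinates are given. It named 87.4% of the identifiers and 97.4% of the 8033 genes above the filter described below. No spike-in values were used here, so all levels are relative to the other RNA in the same oocyte.

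Depth was worked out from the table, because low FPKM values are whole multiples of a single step per gene and library. Read counts were recovered for all 18300 genes with a value, as whole numbers within a tolerance of 0.01, but for the 2437 genes seen in 1 library only the count is not determined and was taken as the smallest possible. The counts are the smallest that fit, so a factor common to all libraries of a gene would be missed. The library divisors that go with these counts imply gene lengths at a median of 1.09 times those of the reference. Of 13858 genes compared, only 37.5% had an implied length within 20% of the reference's. The lengths thus do not check the counts gene by gene, nor the intervals and floors that rest on them. On simulated FPKM the procedure returned 99.3% of 2806 genes exactly. Reads in genes came to 17352260 in WT1, 20077129 in WT2, 15340782 in WT4, 15887904 in KO1, 19762797 in KO2, 25940519 in KO3 and 21569030 in KO4. These reads made up 82.2% to 85.2% of the divisor. Intervals on read counts are exact 95% Poisson or binomial intervals and cover counting error only, since reads from amplified cDNA without molecular identifiers are not independent molecules. Between libraries of the same genotype the chi-square per gene was 51.2 to 105, so libraries differed by far more than counting error. This does not separate differences between oocytes from those of amplification.

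Each library is 1 cell and the labels name no animal, so a genotype counts as 1 sample here and no test of the genotype is reported. Tests planned before the data were examined (moderated linear models, gene set tests and exact permutation tests over oocytes) were run and left out for that reason. Values are given as the mean ± SD over oocytes (n = 3 WT and n = 4 KO), where the SD is the spread between single oocytes and not between animals. "Higher" and "lower" refer to these libraries.

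Genes with FPKM of at least 1 in at least 3 libraries were compared as the difference of mean log2(FPKM + 1), KO minus WT. The filter, the pseudocount of 1, the 19 gene lists and most alternatives were set before the data were examined. The naming rule was also set then, but it was changed after values had been seen. Its condition on a test was removed, and its choice within lists by smallest p was replaced by the size of the difference. The rule now takes, per direction, the 12 genes with the largest log2 difference among those with every KO oocyte on the same side of every WT oocyte and an informative symbol. From each list with at least 5 genes above the filter it takes the 2 with the largest absolute difference. Genes outside the rule were named for their level or function after their values were seen: Asf1a, Nasp, Dppa3, Btg4, Spin1, Tet3, Setd2, Espl1, Incenp, Cpeb1, Rpl17, Sdha, Mest, Gtf2b, Arid1a, Hsf1, Sod1, Cyp19a1, Serpine2, Cpa1, Ms4a1, Odf1, Vmn1r139, Slc2a3, Pgam1, Ddit4, Pgk1 and Gapdh. Differences of 2-fold and 4-fold are on the log2(FPKM + 1) scale, as are those of 1.5-fold within lists. Ratios quoted for single genes are ratios of mean FPKM. These size limits were chosen after values had been seen.

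Each list's median difference was placed among the medians of 10000 random lists of the same size. Each member was replaced by a gene drawn from the 100 on either side of it in mean level. The percentile describes these libraries alone and treats genes as independent, and it was added after values had been seen. On shuffled differences, 4.0% of 100 lists of 40 genes fell outside the central 95%, and all 20 lists shifted by -0.4 were found. Some genes belong to several lists, such as Dppa3 and Btg4. Shared sequence was measured as the percentage of a gene's distinct stretches of 31 bases that stand in a reference transcript of another gene, for 83 of the 92 genes over 4-fold apart and 976 random genes.

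The alternatives were pseudocounts of 0.1 and 5, no filter, a filter at FPKM 10, quantile normalization, median-ratio scaling, other detection limits, the 90th to 10th percentile range, Spearman's correlation, the shared numbers 1, 2 and 4 as a block, and leaving out each oocyte in turn. Thinning every library to 15340782 reads, median-ratio scaling of detected genes and of the range, the pairs set against pairs or single oocytes, the bins by level, the search for shared sequence and the hypoxia and glycolysis list were added after seeing the data. Robust variance, array weights, an estimated correlation and a rotation test were settings of the tests that were run and are not reported. Scaling to spike-ins was not run. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and matplotlib 3.10.9 drew the plots.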

Results

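Transcript levels were compared between 3 WT and 4 KO single MII oocytes of the mouse. The comparison asks how the transcriptome of a mature oocyte differs when Hira, which encodes a chaperone for the histone variant H3.3, is deleted during oocyte growth. Reads in genes ranged from 15340782 to 25940519 per oocyte. No animal is named for any oocyte, so the differences below describe these 7 libraries and no test is reported.

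Hira transcripts were lower in every KO oocyte than in every WT oocyte. The level was 0.317 ± 0.028 FPKM in WT and 0.078 ± 0.036 FPKM in KO oocytes, which is 4.04-fold lower and 24.7% of the WT level. WT1, WT2 and WT4 held 42, 55 and 35 Hira reads, and KO1 to KO4 held 12, 15, 5 and 17. The sums were 132 reads (95% interval 110 to 157) against 49 (36.3 to 64.8), a rate 4.31 times as high in WT (3.09 to 6.12). These values cover the whole gene, so they do not separate the deleted part from exons that a conditional allele leaves in place. Hira was below the expression filter in both genotypes, and its difference of -0.29 on the log2(FPKM + 1) scale is compressed by the pseudocount.

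The KO oocytes held transcripts of more genes than the WT oocytes and had a flatter profile. Genes with FPKM of at least 1 numbered 7862 ± 247 in KO and 7132 ± 164 in WT oocytes, and every KO oocyte was above every WT oocyte. The difference of 730 genes was 406 with median-ratio scaling (7720 ± 117 against 7314 ± 34.2). The 50 most abundant genes took 21.2% ± 1.41 of reads in KO and 25% ± 1.57 in WT oocytes. The SD of log2(FPKM + 1) over genes above the filter was 1.86 ± 0.028 in KO and 1.96 ± 0.012 in WT oocytes, again without overlap, but with no filter the difference turned to +0.0083.

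**Figure D1:**
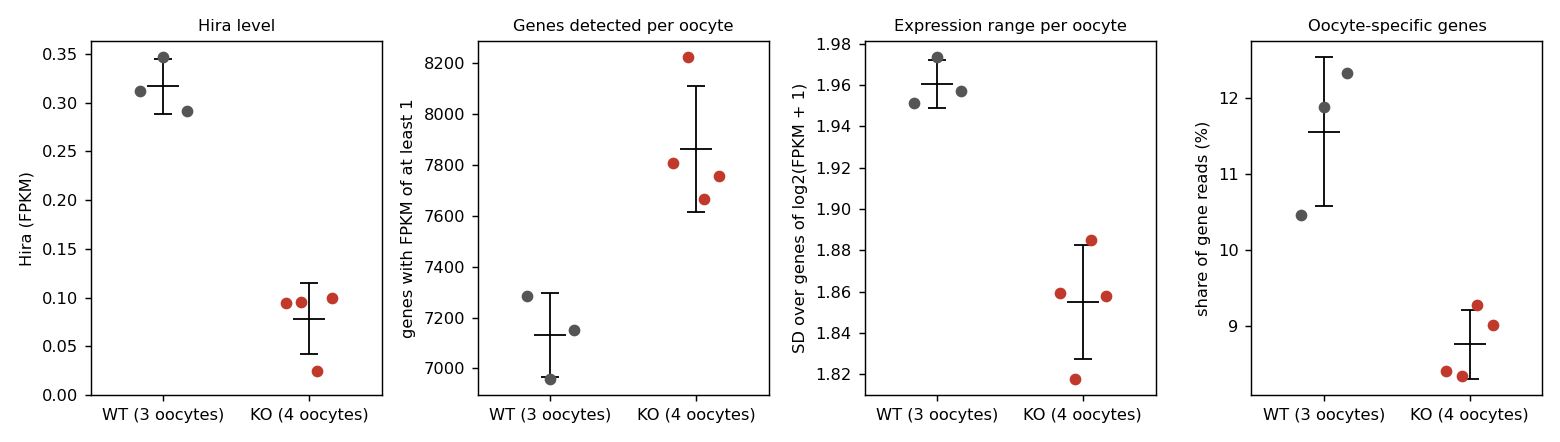
Hira level (FPKM), number of genes with FPKM of at least 1, SD over genes of log2(FPKM + 1) and the percentage of gene reads from oocyte-specific and maternal-effect genes, with 1 point per oocyte and bars for the mean ± SD. In each panel the 3 WT and 4 KO oocytes do not overlap; only the Hira axis starts at 0.

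The median difference fell as expression level rose, and it was negative only for genes with a mean FPKM of 100 and over. It was 0.04 for genes at 30 to 100. The bins were made on the deposited FPKM alone. Median-ratio scaling moved the median of all genes from 0.18 to 0.02, so the level at which the sign changed depends on the scale. Of the 2850 genes with a mean FPKM under 3, 24.6% were over 1.5-fold higher in KO and 6.67% over 1.5-fold lower, with a median difference of 0.25. Of the 362 genes with a mean FPKM of 100 and over, 4.97% were over 1.5-fold higher and 17.1% over 1.5-fold lower, with a median of -0.13. In this top bin the median against the WT mean was -0.15 in KO1, -0.15 in KO2, -0.07 in KO3 and -0.14 in KO4. Each WT oocyte set against the other WT oocytes lay between 0.00 and 0.03 there, and between -0.13 and 0.12 in the lowest bin.

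**Figure D2:**
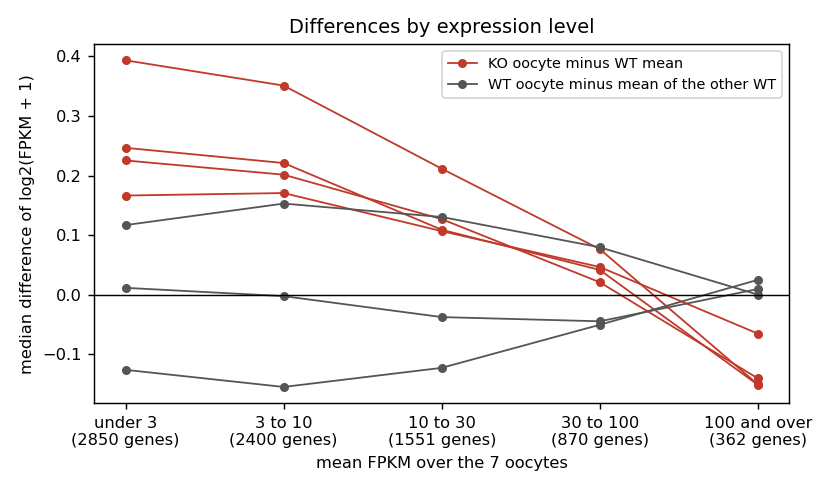
Median difference of log2(FPKM + 1) for genes binned by mean FPKM, for each KO oocyte against the WT mean (red) and each WT oocyte against the mean of the other WT oocytes (grey). The 4 KO lines go from positive in the lowest bin to negative in the bin at 100 and over, where the WT lines lie near 0.

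Of the 8033 genes above the filter, 827 were over 2-fold apart, 639 higher and 188 lower in KO oocytes. Over 4-fold apart were 92 genes, 73 higher and 19 lower. The surplus of higher genes was smaller with other scalings. The median of all genes was 0.18 in the deposited FPKM, -0.01 after quantile normalization and 0.02 after median-ratio scaling. Those scalings gave 376 higher and 309 lower genes, and 448 higher and 313 lower genes. Over 2-fold apart in all 3 scalings were 355 higher and 180 lower genes. For comparison, the 3 ways of setting KO pairs against each other gave 149 to 246 genes over 2-fold apart, and WT pairs against KO pairs gave 806 to 1350. A pair against a single oocyte gave 386 to 637 within WT, 277 to 478 within KO and 919 to 1661 between genotypes. The first principal component (48.4% of variance) had all WT oocytes on the negative and all KO oocytes on the positive side, and the second (14.6%) did not part the genotypes.

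The genes highest above WT included Mt1, Cox4i2 and Efna1. Mt1, a metallothionein that binds zinc and other metals, was at 77.6 ± 19.8 FPKM in KO and 0.119 ± 0.205 in WT oocytes, where it had 10 reads, all in WT2. Cox4i2, an alternative form of subunit 4 of cytochrome c oxidase, was 21.6-fold higher (79.4 ± 17.5 against 3.67 ± 1.94). Efna1, a ligand of Eph receptors, was 24.4-fold higher (58.0 ± 18.9 against 2.38 ± 1.27). Cdo1, which starts the breakdown of cysteine, was 10-fold higher (46.4 ± 11.3 against 4.65 ± 2.56). Mpv17l was 21.5-fold higher (23.7 ± 2.45 against 1.10 ± 0.551), and Tapbpl, a tapasin-related protein of peptide loading, was 8.11-fold higher (33.1 ± 12.9 against 4.08 ± 3.23). Pdha2, the testis form of a pyruvate dehydrogenase subunit, was 8.54-fold higher. Cd7, a lymphocyte surface protein, was 7.06-fold higher, and Zscan26, a zinc finger gene, 10.4-fold higher. Also among the 12 were members of chemoreceptor families: Vmn1r132 (14.3 ± 4.41 against 2.25 ± 3.89, with 405 of its 406 WT reads in WT4), Olfr1174-ps (19.9 ± 6.63 against 2.09 ± 0.849) and Vmn2r-ps111. The last was at 0 in all WT oocytes and 5.26 ± 1.38 in KO, at least 160.6-fold higher against a floor of 3 reads over the group.

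The genes furthest below WT included Hormad1, a protein of the meiotic chromosome axis, at 0.855 ± 0.322 FPKM in KO and 21.8 ± 0.330 in WT oocytes (25.6-fold). Hist1h2al, a histone H2A sequence that the annotation lists as a processed pseudogene, had 324 reads in WT and 1 in KO, a rate ratio of 519 (92.5 to 20555). Tuba3b, an alpha tubulin, had 846 reads in WT and 7 in KO, and Rps3a3, a copy of a ribosomal protein gene, had 243 and 2, a ratio of 195 (53.3 to 1616). Mfap1b was 9.76-fold lower (2.57 ± 0.353 against 25.1 ± 2.87). Rgn, a calcium-binding protein, was 5.33-fold lower (8.94 ± 3.41 against 47.7 ± 2.15). Cltrn, the kidney protein collectrin, was 11.4-fold lower, and Bbs7, of the ciliary BBSome, was 6.48-fold lower. Cmtm8 (66.2 ± 17.3 in WT), Tmem74 (52.1 ± 17.7), Prr32 (37.4 ± 2.79) and Cldn34b2 (49.9 ± 6.18) were 5.05-, 4.68-, 4.62- and 4.60-fold lower. Hormad1 shares 36.3% of its sequence with other genes, against a median of 0.51% for random genes. The receptor, histone and tubulin genes, Rps3a3, Mfap1b and Cldn34b2 also share much of theirs. Reads of all these genes cannot be assigned with certainty. All 24 genes were over 2-fold apart under quantile normalization and median-ratio scaling as well.

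**Figure D3:**
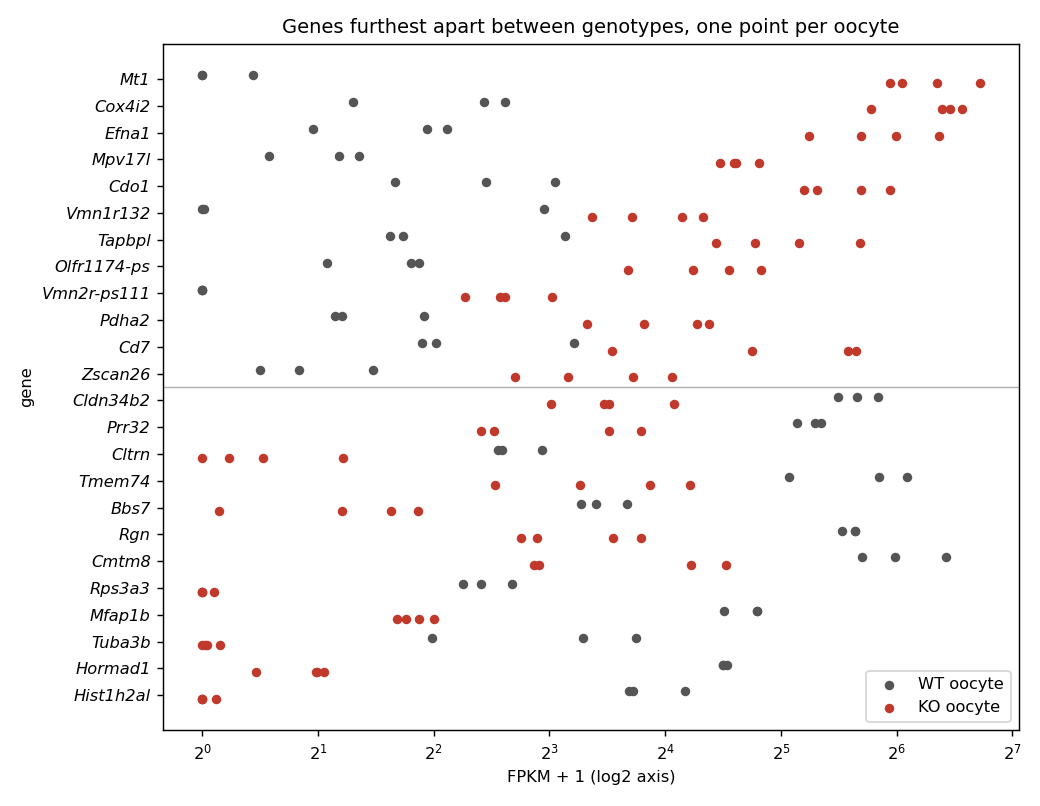
FPKM + 1 on a log2 axis for the 12 genes furthest above and the 12 furthest below WT, with 1 point per WT (grey) and KO (red) oocyte. For each gene shown every KO oocyte lies on the same side of every WT oocyte, which was a condition for being named.

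In the list of the HIRA complex and H3.3 handling, which also holds general histone chaperones, several genes other than Hira were higher in KO oocytes. Of 18 genes above the filter, 5 were over 1.5-fold higher and none over 1.5-fold lower, and the median difference was 0.41 (0.38 with quantile normalization and 0.21 with median-ratio scaling). Among all genes above the filter, 4.97% to 27.5% per level bin were over 1.5-fold higher and 6.67% to 17.1% lower. Counts of members in this and the other lists are to be read against those shares. Set, a histone chaperone, was at 23.7 ± 4.27 FPKM in KO and 11.9 ± 1.54 in WT, and Daxx, which deposits H3.3 at heterochromatin, at 4.86 ± 0.431 and 2.25 ± 1.07. The H3 chaperones Asf1a (67.8 ± 19.5 against 37.0 ± 12.2) and Nasp (77.8 ± 9.97 against 48.4 ± 5.13) were higher too. The list's median lay at percentile 99.6 of level-matched random lists. It was 94.4 without WT4 and 97.4 without KO4, inside the central 95%.

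Histone variants and chromatin regulators showed single genes that stood higher without a shift of the list. Of 14 histone variant and linker histone genes, 5 were over 1.5-fold higher and none lower, with a median of 0.26 (0.27 with quantile normalization and 0.05 with median-ratio scaling). The percentile was 86.0, and 97.7 with a pseudocount of 5. The linker histone gene Hist1h1e was at 14.7 ± 4.37 FPKM in KO and 2.28 ± 1.49 in WT oocytes, and 34.7% of its sequence is shared with other genes. H2afz, the H2A.Z gene, was at 24.4 ± 2.52 and 8.28 ± 2.70. Of 57 chromatin remodellers and histone modifiers, 8 were over 1.5-fold higher and none lower, with a median of 0.19 (0.05 with quantile normalization and 0.02 with median-ratio scaling). The percentile was 51.8, and 86.6 without WT1, where the median was 0.34. The remodeller genes Baz1a (16.2 ± 2.31 against 8.49 ± 2.75), Chd4 (9.78 ± 1.52 against 4.98 ± 1.49) and Arid1a (23.2 ± 6.10 against 12.6 ± 3.64) were higher. Of 20 genes of the DNA methylation machinery, 6 were over 1.5-fold higher and 1 lower, with a median of 0.19 (0.08 with quantile normalization and 0.06 with median-ratio scaling). The percentile was 66.8, and 27.1 without WT2, where the median was 0.01. It was 85.5 with a pseudocount of 0.1 (median 0.31) and 95.2 with a filter at FPKM 10 (median 0.33). Trim28, a corepressor that protects methylation at imprints, was at 26.0 ± 2.11 in KO and 11.5 ± 3.29 in WT. The methyltransferase Dnmt3a was at 4.40 ± 1.17 and 1.49 ± 0.546, the oxidase Tet3 at 106 ± 15.3 and 69.8 ± 9.97 (a difference of 0.59 that was 0.38 with median-ratio scaling), and the H3 lysine methyltransferase Setd2 at 17.2 ± 2.03 and 10.6 ± 1.02.

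A part of the oocyte-specific and maternal-effect genes was lower in KO oocytes. Of 48 genes, 12 were over 1.5-fold lower, 2 over 1.5-fold higher and the others within 1.5-fold, and 18 had a positive difference. Their share of reads was 8.77% ± 0.454 in KO and 11.6% ± 0.974 in WT oocytes, without overlap. Dppa3, which protects the maternal genome from demethylation after fertilization, was at 5718 ± 1020.1 FPKM in KO and 9676 ± 285 in WT. Btg4, an adapter for the decay of maternal mRNA, was at 2148 ± 136 and 3548 ± 271, and Spin1, a chromatin reader, at 1560 ± 246 and 3041 ± 717. The zona pellucida gene Zp2 was at 60.3 ± 24.3 and 120 ± 45.5, with overlap between single oocytes. Gpr3, the receptor that holds meiotic arrest, was at 1.45 ± 0.748 and 3.66 ± 1.25. The list's median was -0.26 (-0.14 with quantile normalization and -0.46 with median-ratio scaling), at percentile 0.47 of level-matched random lists. It moved inside the central 95% without WT1 (7.23), WT4 (3.48), KO1 (7.91) or KO4 (4.08). Dppa3, among the most abundant transcripts, differed by -0.77 as deposited and by -0.19 under quantile normalization, which draws the top of each profile together.

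Genes of meiosis and of maternal mRNA use included members well above WT, with list medians near that of other genes. Of 50 meiosis and spindle checkpoint genes, 12 were over 1.5-fold higher and none lower. The median was 0.09 at percentile 53 (0.04 with quantile normalization). It turned to -0.09 with median-ratio scaling and to -0.0046 without KO3, at percentile 21.9, and was 0.005 without WT2. Wee1, a kinase that inhibits CDK1, was at 2.07 ± 0.833 FPKM in KO and 0.246 ± 0.401 in WT oocytes, with 28 of its 29 WT reads in WT1. Cdc16, of the anaphase-promoting complex, was at 5.72 ± 1.69 and 1.87 ± 1.42 with overlap. Espl1, the protease separase, was at 16.8 ± 2.61 and 6.88 ± 2.54, and Incenp, of the chromosomal passenger complex, at 12.5 ± 1.19 and 5.87 ± 2.21. Of 35 genes of mRNA translation and decay, 8 were over 1.5-fold higher and 3 lower. Their median was 0.19 at percentile 82.5, was 0.11 with quantile normalization and turned to -0.01 with median-ratio scaling. Ddx6, an RNA helicase of mRNA storage, was at 7.71 ± 1.60 in KO and 1.67 ± 0.559 in WT, the poly(A)-binding protein gene Pabpc1 at 4.43 ± 1.41 and 0.671 ± 0.398, and Cpeb1 at 21.4 ± 4.44 and 10.2 ± 3.12. Of 29 DNA damage and p53 genes, 6 were over 1.5-fold higher and none lower, with a median of 0.16 at percentile 47.8. The median was 0.08 with quantile normalization, at percentile 82.1, and 0.02 with median-ratio scaling. The end-joining ligase Lig4 was at 20.6 ± 3.23 in KO and 7.75 ± 0.525 in WT, and Mdc1 at 2.97 ± 0.394 and 1.38 ± 1.23 with overlap.

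Ribosomal protein genes went both ways and lay low as a list. Of 69 genes, 9 were over 1.5-fold higher and 10 lower, with a median of -0.04 against 0.18 for all genes (-0.25 with quantile normalization and with median-ratio scaling). Rpl34 was at 14.2 ± 4.30 FPKM in KO and 34.1 ± 5.31 in WT oocytes, and Rpl17 at 162 ± 28.2 and 285 ± 31.6. Rplp1 was at 255 ± 85.6 and 123 ± 66.1 with overlap, and its difference of 1.18 was 0.60 without WT2. The list lay at percentile 0.53, and at 8.57 without KO4, where its median was 0.04. The median was -0.15 without WT2, -0.12 without WT4 and -0.17 without KO2. The list of RNA polymerase II and general transcription factors held 47 genes, 6 over 1.5-fold higher and 5 lower. Its median was -0.03 at percentile 3.41 (-0.17 with quantile normalization and -0.23 with median-ratio scaling). The percentile was 1.68 with quantile normalization, 2.41 with no filter, 2.09 without WT2 and 2.38 without KO3. It was 5.05 without KO1, 7.21 with a filter at FPKM 10 and 6.67 without WT1, where the median was 0.01. Taf4b, an oocyte-rich TFIID subunit, was at 15.1 ± 1.62 in KO and 5.27 ± 1.59 in WT. Gtf2a1, of TFIIA, was at 106 ± 19.9 and 225 ± 58.0, and Gtf2b, which encodes TFIIB, at 289 ± 36.5 and 483 ± 19.2 (a difference of -0.75 that was -0.49 with quantile normalization).

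Nuclear genes of oxidative phosphorylation numbered 66, of which 11 were over 1.5-fold higher and 5 lower. The complex I genes Ndufa5 (28.9 ± 11.2 against 7.20 ± 3.02 FPKM) and Ndufa7 (5.50 ± 2.97 against 0.955 ± 0.658) were higher in KO, and Sdha, of complex II, was lower (10.6 ± 0.294 against 19 ± 2.08). The median was 0.00 as deposited, -0.15 with quantile normalization and -0.18 with median-ratio scaling, at percentile 2.77 as deposited. The percentile left the central 95% without WT1 (2.0), WT2 (0.28), KO2 (1.38) or KO3 (1.22), with no filter (1.19) and with a pseudocount of 5 (2.11). It moved further in without WT4 (16.8, median 0.08), KO1 (19.7, median 0.09) or KO4 (12.9, median 0.06) and with a filter at FPKM 10 (21.7). Of 14 mitochondrially encoded genes, 1 was over 1.5-fold lower and none higher. The list took 3.09% ± 0.793 of reads in KO and 2.81% ± 0.393 in WT oocytes, which overlapped. mt-Nd2 was at 677 ± 263 in KO and 981 ± 60.6 in WT, and mt-Atp8 at 212 ± 85.9 and 293 ± 29.2, both with overlap. The list's median of 0.08 was 0.34 with quantile normalization and turned to -0.14 with median-ratio scaling, and its percentile of 98.0 was 94.2 with no filter, 91.6 without WT2 (median -0.02) and 75.4 without KO1 (median -0.10).

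**Figure D4:**
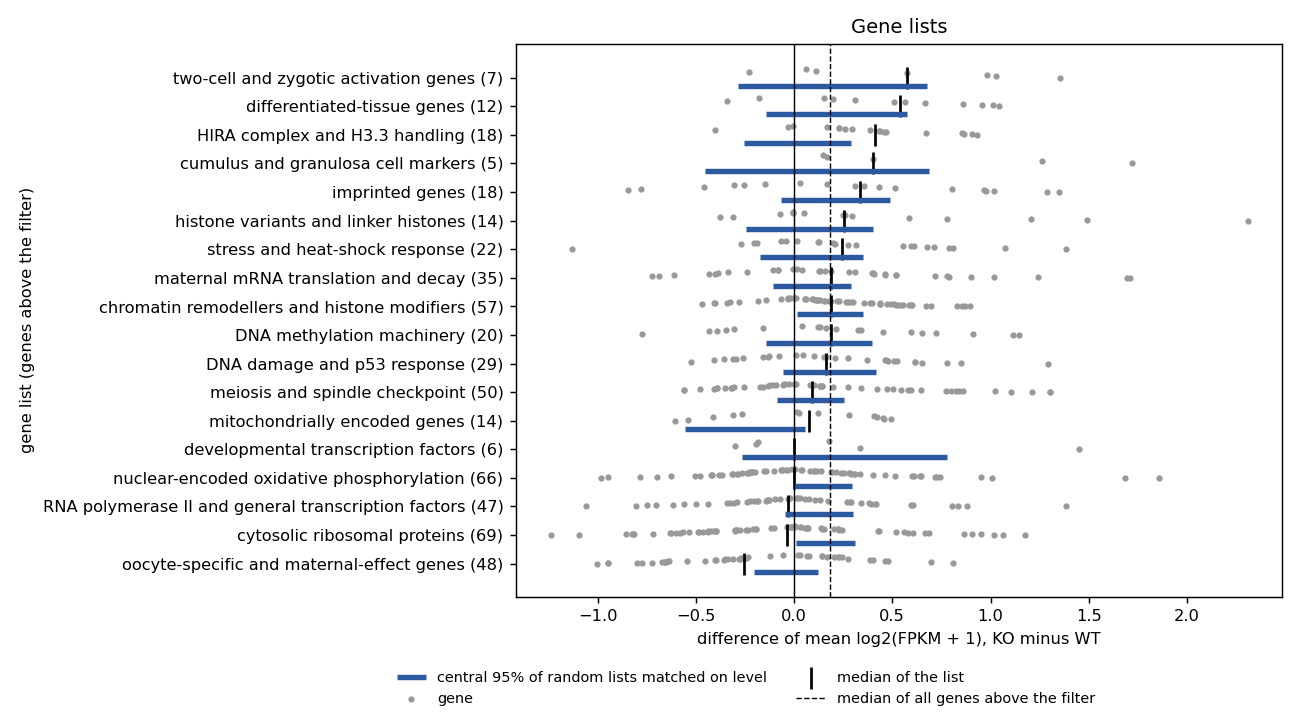
Differences of mean log2(FPKM + 1), KO minus WT, for each gene (grey points) of 18 lists, with the list median (black tick), the central 95% of medians of level-matched random lists (blue bar) and the median of all genes (dashed line). Outside the bar are the lists of H3.3 handling and mitochondrially encoded genes (above) and of oocyte-specific and ribosomal protein genes (below); the mitochondrially encoded median turns negative with median-ratio scaling.

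The count of lists outside the central 95% was 4, and it was 7 without KO3 and 1 without KO4.

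Most markers of other cells were below FPKM 1 in both genotypes. Of 38 cumulus and granulosa cell markers, 33 had a mean FPKM under 1 in both genotypes and 5 were above the filter. Fshr, the FSH receptor gene, was at 0 in the WT oocytes and in KO1 but at 2.96 ± 2.09 over the KO oocytes, at least 145.7-fold higher against a floor of 3 reads over the WT group. Nr5a2, a nuclear receptor gene, was at 7.25 ± 0.904 in KO and 2.53 ± 0.994 in WT. Serpine2 (245 ± 31.2 against 218 ± 36.1) and Cyp19a1 (24.6 ± 3.77 against 22.0 ± 1.78) were abundant in both genotypes, overlapped, and turned lower in KO with median-ratio scaling (-0.04 and -0.06). The Serpine2 difference of 0.17 was 0.34 with quantile normalization, 0.03 without WT1, and 0.26 without WT2 and without KO1. The Cyp19a1 difference of 0.15 was 0.01 with quantile normalization, 0.10 without WT4, 0.06 without KO1 and 0.24 without KO4. The 5 genes had a median of 0.40, also with Fshr at the floor of 3 reads, at percentile 85.8 (0.34 with quantile normalization and 0.24 with median-ratio scaling). Of 26 blood and immune markers only Ms4a1 was above the filter (41.3 ± 9.81 in KO and 46.8 ± 7.24 in WT), and its difference of -0.20 was -0.41 with median-ratio scaling, -0.32 without WT1, -0.10 without WT4 and -0.02 without KO1.

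Genes of differentiated tissues and developmental transcription factors were somewhat more often detected in KO oocytes, with overlap. All genes were more often detected too: at FPKM of at least 0.1, 12252 ± 375 were detected in KO and 11413 ± 206 in WT oocytes. Relative to the WT count, these lists gained more than all genes did, but genes of similar low level were not compared. Detection at this limit also depends on depth, and the counts of all genes and of transcription factors were not thinned to equal reads. Of 98 differentiated-tissue genes, 23.8 ± 1.71 had FPKM of at least 0.1 in KO and 20.7 ± 1.53 in WT oocytes. The difference of 3.08 genes was 2.33 at equal reads in genes and -0.33 at FPKM of at least 10. Of 100 developmental transcription factors, 20 ± 2.83 were detected in KO and 15.7 ± 1.53 in WT oocytes. The difference of 4.33 was 0.33 at FPKM of at least 1 and at FPKM of at least 10. Among 12 tissue genes above the filter, 5 were over 1.5-fold higher and none lower, with a median of 0.54 (0.26 with quantile normalization and 0.42 with median-ratio scaling). The percentile was 96.1, which was 97.7 without KO1 and 98.3 without KO3 but 84.2 without WT1. Syt1, a synaptic vesicle protein, was at 6.54 ± 1.18 in KO and 2.74 ± 1.16 in WT, the fatty acid transporter Cd36 at 27.5 ± 5.94 and 13 ± 2.28, and the pancreatic enzyme gene Cpa1 at 182 ± 19.4 and 116 ± 25.3. Odf1, of the sperm tail, was the only tissue gene with a mean FPKM of at least 1 in KO and not in WT (1.17 ± 0.738 against 0.548 ± 0.635, with overlap). Its difference of 0.51 was 0.24 with quantile normalization and without WT4. Among 6 developmental transcription factors above the filter, Gata3 was over 1.5-fold higher (36.2 ± 5.32 against 13.3 ± 5.94). Isl1 was at 1.01 ± 0.661 in KO and 0.584 ± 0.563 in WT with overlap, a difference of 0.34 that was -0.01 with quantile normalization, 0.13 without WT1 and 0.55 without KO1. The median of these 6 was 0.00 at percentile 16.6 (-0.28 with quantile normalization and -0.14 with median-ratio scaling), and the percentile was 2.33 without WT2 (median -0.33), 41.5 without WT4 (median 0.18) and 70.1 with no filter. Of 7 genes of the 2-cell stage and zygotic activation, 3 were over 1.5-fold higher and none lower, with a median of 0.58 (0.34 with quantile normalization and 0.41 with median-ratio scaling). The percentile was 94.3, which was 99.5 without WT4 and 99.0 without KO1 but 69.8 without WT2 (median 0.27) and 77.3 without KO2 (median 0.36). Zscan4d was at 6.34 ± 5.25 in KO and 1.16 ± 0.857 in WT with overlap, and its difference of 1.35 was 2.08 without KO1. Zfp809, a repressor of retroviruses, was at 2.56 ± 0.953 and 0.716 ± 0.300.

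By correlation, single oocytes of the same genotype were about equally alike in both genotypes. By genes over 2-fold apart, a pair against a single oocyte gave 386 to 637 within WT and 277 to 478 within KO, ranges that overlap. The mean pairwise Pearson correlation over genes was 0.958 among KO oocytes (0.950 to 0.965) and 0.953 among WT oocytes (0.949 to 0.960), against 0.917 between genotypes (0.906 to 0.929). Genes are not independent replicates, and the difference of 0.0048 turned to -0.0022 without WT1 and was 0.0088 without WT4 and 0.0090 without KO1.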

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

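Each measure and named gene was looked at in the 4 KO oocytes for an oocyte far from the other 3, defined as a gap to its nearest neighbour, as a share of the group's range, above Dixon's 95% critical value. Of 95 such groups 9 had an oocyte this far out. Chance gives about 1 in 20 for independent, normally distributed groups. Some groups here are related or hold tied values, so no excess over chance can be read from the 9. The WT group of 3 was not looked at in this way. No cause was tested for any of them.

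For Hira, KO3 was at 0.024 FPKM and the other KO oocytes at 0.0941 to 0.0997, a gap of 0.926 of the range, on 5 reads against 12 to 17. Hist1h2al and Rps3a3 were at 0 in the other KO oocytes and had 1 and 2 reads in KO3, so both gaps are 1.0 by construction. The remaining values are log2(FPKM + 1). Hormad1 was at 0.46 in KO1 and 0.98 to 1.06 in the others (0.879). Gab1, an imprinted gene that encodes a docking protein, was at 1.68 in KO3 and 1.31 to 1.32 in the others (0.952). Asf1a was at 6.62 in KO1 and 5.86 to 5.90 in the others (0.955). Tet3 was at 6.4 in KO3 and 6.81 to 6.88 in the others (0.870). Cpa1 was at 7.73 in KO4 and 7.42 to 7.45 in the others (0.909). Each of these oocytes lay on the same side of every WT oocyte as the rest of the KO group. Pgam1, a glycolysis gene, was at 1.27 in KO3 and 2.26 to 2.36 in the others (0.913), and here KO3 lay within the WT range.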

How the results depend on the processing

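The settings for thinning and for median-ratio scaling of detected genes and of the range were chosen after the result was seen. Where a cause is not named, the cause was not tested. All 827 genes over 2-fold apart kept their direction in each setting where they passed the filter, but genes chosen for large differences seldom change sign. Of these, 554 stayed over 2-fold apart with quantile normalization, 636 with median-ratio scaling and 209 with a pseudocount of 5. Named genes kept their direction in 1174 comparisons, and 3 reversed: Isl1 with quantile normalization (-0.0075) and Cyp19a1 (-0.057) and Serpine2 (-0.042) with median-ratio scaling. A larger pseudocount shrinks differences by construction, and a filter at FPKM 10 leaves fewer genes. Robust variance, array weights, an estimated correlation and a rotation test belong to the tests that were run and are not reported, and scaling to spike-ins was not run. Depth limits genes near the floor, such as Hira with 5 to 17 reads per KO oocyte.

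With a pseudocount of 0.1, 1681 genes were over 2-fold apart (1303 higher and 378 lower), the Hira difference was -1.25 and that of the range -0.21. With a pseudocount of 5 these were 209 (148 and 61), -0.066 and -0.049. The filter at FPKM 10 gave 276 genes (201 and 75), a range difference of -0.16 and a spread difference of 0.0134. Quantile normalization gave 376 higher and 309 lower genes and a Hira difference of -0.41. Median-ratio scaling gave 313 lower genes, 406 more detected genes and a range difference of -0.14. With no filter the range difference reversed to 0.0083, and the 90th to 10th percentile gave -0.26. Spearman's correlation gave a spread difference of 0.0120.

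Detection at FPKM above 0 gave 1011 more genes in KO and 1.17 more tissue genes. This limit depends directly on depth, and its counts were not thinned to equal reads. A limit of 1 gave 0.833 more tissue genes and 0.333 more transcription factors. A limit of 10 gave 251 more genes, -0.333 tissue genes and 0.333 more transcription factors. Leaving out each oocyte in turn, 1 (without KO4) to 7 (without KO3) lists lay outside the central 95%, and the spread difference was -0.0022 (without WT1) to 0.0090 (without KO1). List medians without each oocyte in turn, and in brackets with other pseudocounts and filters, were: H3.3 handling 0.26 to 0.59 (0.26 to 0.44), oocyte-specific -0.32 to -0.15 (-0.27 to -0.23), DNA methylation 0.01 to 0.26 (0.12 to 0.33), histone variants 0.17 to 0.29 (0.08 to 0.26), chromatin regulators 0.14 to 0.34 (0.14 to 0.24), DNA damage 0.12 to 0.22 (0.14 to 0.20), meiosis -0.0046 to 0.15 (0.00 to 0.12), mRNA use 0.15 to 0.26 (0.14 to 0.20), ribosomal -0.17 to 0.04 (-0.30 to -0.02), oxidative phosphorylation -0.09 to 0.09 (-0.01 to 0.02), mitochondrially encoded -0.10 to 0.23 (0.03 to 0.08), RNA polymerase II -0.09 to 0.01 (-0.09 to -0.03), imprinted 0.31 to 0.48 (0.05 to 0.49), stress 0.17 to 0.35 (0.10 to 0.26), 2-cell 0.27 to 0.87 (0.20 to 0.69), cumulus (where 5 genes passed the filter) 0.27 to 0.42 (0.03 to 0.49), tissue 0.46 to 0.63 (0.08 to 0.75) and developmental transcription factors -0.33 to 0.18 (0.00 to 0.02).

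The labels do not say that equal numbers share an animal. With the numbers 1, 2 and 4 taken as a block (the mean of the differences within each number, which for genes and lists equals leaving out KO3), 873 genes were over 2-fold apart (669 higher and 204 lower). The Hira difference was -0.26, the range difference -0.12, and KO held 796 more detected genes, 3 more tissue genes and 3.67 more transcription factors. The lists outside the central 95% were 7. Deviations from the group mean correlated at 0.107, -0.116 and -0.044 for equal numbers, and only WT1 and KO1 correlated best with their own number.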

Other observations

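All of the tests below were chosen after the result was seen: those of depth, scale, separate libraries, gene length, GC content, cumulus markers, neighbouring genes, close copies, the level of the oocyte list and hypoxia. For depth, scale, separate libraries, gene length and GC content the bounds were written before the test was run. For cumulus markers, neighbouring genes, close copies, the level of the oocyte list and hypoxia they were written after values had been seen.

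Imprinted genes and stress genes included members that stood apart in both directions. Of 18 imprinted genes above the filter, 6 were over 1.5-fold higher in KO oocytes and 2 lower, with a median of 0.33 at percentile 81.0 (0.06 with quantile normalization and 0.20 with median-ratio scaling). Igf2r, a receptor that clears IGF2, was at 21.5 ± 4.18 FPKM in KO and 7.75 ± 0.722 in WT. Gab1 was at 1.67 ± 0.355 and 0.093 ± 0.136, with 29 of its 32 WT reads in WT2, and Mest was at 9.92 ± 1.34 and 18.1 ± 5.17. Of 22 stress and heat-shock genes, 8 were over 1.5-fold higher and 1 lower, with a median of 0.24 at percentile 89.1 (0.18 with quantile normalization and 0.05 with median-ratio scaling). The heat-shock factor genes Hsf2 (7.01 ± 1.81 against 2.09 ± 0.867) and Hsf1 (16.8 ± 4.39 against 7.67 ± 3.17) and the superoxide dismutase gene Sod1 (375 ± 78.4 against 210 ± 13.2) were higher. Nfe2l2, which encodes the antioxidant regulator NRF2, was lower (3.06 ± 1.05 against 7.79 ± 1.92).

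KO oocytes had more genes at FPKM of at least 1. At equal reads in genes the difference was 736 genes, still without overlap. FPKM is already scaled to the reads of the library, so thinning could hardly change this count and is a weak test of depth. It does not show how many distinct molecules each library sampled. For cells of the follicle, only 1 of 38 cumulus and granulosa markers (Fshr) passed FPKM 1 in KO alone, and 33 stayed under it in both genotypes. The markers thus show no broad signal of such cells. The bound for this was written after values had been seen, so a small contribution stays open. The scale stays open: with median-ratio scaling 406 genes remained, which is less than the prediction required to set it aside, although the genotypes still did not overlap. The genotype may account for the rest, but no animal is named and animal, lane and day could not be told apart from it.

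The difference between genotypes went down as the level went up (Spearman's rho over genes -0.15, and -0.13, -0.18, -0.08 and -0.13 for KO1 to KO4 against WT). Regression to the mean is argued against, since rho was -0.13 with level and difference taken from separate libraries, and each WT oocyte against the others gave -0.02 to 0.03. Gene length is argued against as the whole cause, since the weakest rho within length classes of equal size was -0.11. GC content stays open, since the weakest rho within GC classes of equal size was -0.085, between the bounds set for and against it. The oocyte-specific list lay at percentile 0.47 of lists matched on level, but at up to 7.91 without KO1, so its lower level could not be told apart from that of abundant genes in general.

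Of 92 genes over 4-fold apart, 83 had a place in the reference order. For a strain region around a locus, 1 adjacent pair was found (Vmn1r132 and Vmn1r139), and random placements gave a median of 1 and a 95th percentile of 3. These genes share 100% and 73.7% of their sequence with other genes. The count met the bound set against such a region, but that bound was written after values had been seen. Only immediate neighbours over 4-fold apart were counted, which can miss a region, so this cause stays open. Reads shared between close copies stay open: 17.4% of the genes (16) were pseudogenes or members of receptor, histone, tubulin or ribosomal protein families, against 4.24% among all genes. By sequence, 19.3% of 83 genes shared at least 50% of their stretches of 31 bases with another gene, against 3.59% of random genes. Either criterion was met by 26.5%. The 25% set against this cause was written for the family share, and its 17.4% was under it. That bound was written after values had been seen, and the excess by sequence keeps the cause open. Copies may thus account for a part, although the median share per gene was 1.48%, and an effect of the genotype stays untested.

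Cox4i2 and Efna1 are known to respond to low oxygen in other cells, so a hypoxia or glycolysis response was tried as a hypothesis for their higher level. Of 18 other genes of such responses above the filter, 16.7% (Slc2a3, Pgam1 and Ddit4) were over 1.5-fold higher and 1 (Pgk1) was lower, with a median of 0.19. The differences of Pgam1 (0.69) and Ddit4 (0.66) were 0.42 and 0.37 with quantile normalization. Gapdh, a glycolysis gene with 27.2% of its sequence shared with other genes, was 4.59-fold higher (45.0 ± 3.4 against 9.80 ± 3.03). It had been seen beforehand and was left out, and with it the share over 1.5-fold higher was 21.1% of 19. With Cox4i2 and Efna1 as well it was 28.6% of 21, but these genes prompted the hypothesis, so that share cannot bear on it. The 25% set against such a response and the 50% set for it were for the 18 other genes. Their 16.7% was under both, and their median was close to the 0.18 of all genes. Those bounds were written with the values in view, so the hypothesis stays open.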
